A study of Mus musculus with 4 samples.

How the data were processed

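RNA was measured by sequencing in 4 libraries of mouse spleen cells (C57BL/6 background), with 1 library per group. The groups were invariant natural killer T (iNKT) cells and CD44-high CD4+ T cells (CD44hi), each from wild-type (WT) mice and from Ezh2fl/fl CD4-Cre mice (KO), in which Cre recombinase expressed in T cells is meant to delete the floxed part of Ezh2. Per the labels' protocols, iNKT cells were sorted with an antibody to the T cell receptor beta chain and CD1d tetramers loaded with the lipid PBS-57, and CD44hi cells with antibodies to the T cell receptor beta chain, CD44 and CD4. The labels do not say whether tetramer-binding cells were kept out of the CD44hi sort. Per the labels' protocols, RNA was isolated with TRIzol and Picopure columns and libraries were made with the TruSeq RNA kit v2, which does not mark the strand.

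The authors deposited 1 file per library with a gene symbol and an FPKM value (fragments scaled to transcript length and library depth), per the file headers. The submitters' processing notes name Bowtie2 2.0.0, TopHat 1.3.2, Cufflinks 2.0.2 and the genome build mm10, without saying which tool did which step. No header or label gives the gene annotation, any filter or the strand setting, so genes that overlap on opposite strands and genes with near-identical copies cannot be told apart with confidence. The iNKT files list 23720 rows and the CD44hi files 23746. The 26 symbols that a spreadsheet had turned into dates or a bare number occur only in the CD44hi files and were left out. Rows that share a symbol (240 symbols) were summed, and 772 symbols of small RNA genes, whose FPKM over very short lengths is unstable, were left out. The remaining 22486 symbols were used.

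The files give no counts, so the depth was estimated from the steps between low FPKM values, which are multiples of what 1 fragment is worth. Gene lengths came from GENCODE M21, whose GRCm38 assembly is the one called mm10; 90.2% of the 11721 genes at 1 FPKM or more in any library had a length. The steps over genes of at least 3000 bases gave 1.08 times the fragments of WT iNKT for KO iNKT, 3.69 times for WT CD44hi and 4.91 times for KO CD44hi. In a transcript of 2 kilobases, 1 fragment is then worth about 0.103 FPKM in WT iNKT, 0.0960 in KO iNKT, 0.0280 in WT CD44hi and 0.0211 in KO CD44hi. Each ratio printed with an interval has the 95% exact (Clopper-Pearson) interval from the estimated fragments of the 2 libraries. These intervals cover counting error only, not variation between mice or between sorts.

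For each of 4 comparisons the difference of log2(FPKM + 1) was taken between the 2 libraries. This scale understates the differences of genes with low values; folds given in the text are plain ratios of FPKM. A gene was measured in a comparison when its FPKM was at least 1 in at least 1 of the 2 libraries, and was called higher or lower when the difference reached 2-fold on the log2(FPKM + 1) scale. With 1 library per group no difference has a replicate check, and no test, standard error or p-value was computed. The effect of the genotype was compared between cell types by the difference of the 2 log2 differences, by the overlap of the gene lists beside that of independent lists (the product of the list sizes divided by the number of genes measured in both), and by correlation across genes, which are not independent replicates.

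Gene lists were fixed before the data were examined: PRC2 subunits, PRC1 and H3K27 demethylases, CDK inhibitors, developmental regulators known as PRC2 targets, NKT lineage genes, type 1, type 2 and type 17 effector genes, cytotoxic granule genes, NK cell receptors, Treg genes, Tfh genes, naive and lymphoid homing genes, inhibitory receptors, chemokine and trafficking receptors, cytokines, T cell identity genes, immediate early genes, proliferation genes, apoptosis genes, interferon stimulated genes, TGF beta, Notch and Wnt genes, glycolysis, oxidative phosphorylation, ribosomal protein and heat shock genes, sex-linked genes, and markers of B cells, plasma cells, myeloid cells, NK cells and ILC1, CD8 T cells, gamma delta T cells, red cells and platelets, and stromal and endothelial cells. For each list with at least 4 measured members, the median log2 difference is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test of the conditions. Some genes stand in several lists.

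The genes named were chosen by a rule fixed at the same time: per comparison, the 10 with the largest and the 10 with the smallest difference among genes at 5 FPKM or more in at least 1 of the 2 libraries, leaving out unnamed or predicted genes, small RNA genes, immunoglobulin and T cell receptor segments and symbols on several rows; the 5 largest and 5 smallest differences of the effects; up to 4 members per list; and in every case a fixed set of regulators, among them Ezh2, Ezh1, Eed, Suz12, Zbtb16, Tbx21, Gata3, Foxp3, Bcl6, Tcf7 and Cdkn2a. The constant segments of the T cell receptor and the invariant Trav11 and Traj18 segments are not listed in the files.

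Another 7 alternatives were planned: a pseudocount of 0.1 FPKM, no filter on low values, a filter at 5 FPKM, scaling by median ratios, scaling each library to the same sum (TPM), small RNA genes left in, and the highest row per symbol. After the data were seen, 2 more were added: genes above 0 in all 4 libraries, and genes at 5 FPKM or more in an iNKT library. The rule was tested on simulated data made from the real levels and depths. For KO against WT iNKT it recovered 100% of genes changed 4-fold, called 0% of those changed 1.5-fold and called 0.0146% of unchanged genes. This covered 7069 genes at 5 FPKM or more in WT iNKT. Genes below that level, where counting error is larger, were not in this check. The simulation held counting error only, not variation between mice or between sorts. Its share of unchanged genes called is therefore not a rate of false calls in the real comparison. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.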

Results

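The series measured RNA in iNKT cells, an innate-like T cell lineage that recognises lipids on CD1d, and in CD44hi CD4+ T cells, the antigen-experienced fraction of CD4+ T cells, from spleens of WT mice and of mice bred to delete part of Ezh2 in T cells (KO, per the labels). Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places the repressive H3K27me3 mark on chromatin. The 4 libraries answer which genes differ between the genotypes in each cell type, and how iNKT cells differ from CD44hi cells in each genotype. Each group was 1 library, so no difference below has a replicate check. The CD44hi libraries were deeper, at an estimated 3.69 (WT) and 4.91 (KO) times the fragments of WT iNKT, against 1.08 times for KO iNKT. At 1 FPKM or more the libraries held 10234 (WT iNKT), 10516 (KO iNKT), 10942 (WT CD44hi) and 11157 (KO CD44hi) genes. Across genes, log2(FPKM + 1) correlated more closely between genotypes (Pearson r 0.979 in iNKT, 0.990 in CD44hi) than between cell types (0.959 to 0.962). Depth and the rows listed differed between the iNKT and CD44hi files, so any batch between these pairs cannot be told apart from cell type.

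The targeted gene, Ezh2 (GRCm38 chromosome 6, 47530139 to 47595341, minus strand), was listed at 15.3 FPKM in WT iNKT, 16.8 in KO iNKT, 28.9 in WT CD44hi and 18.5 in KO CD44hi. The KO to WT ratio was 1.09 in iNKT (95% counting interval 0.905 to 1.32) and 0.642 in CD44hi (0.595 to 0.693). Cre removes only the floxed part of the gene, and a value over the whole gene keeps reads from the other exons. These values therefore do not check the genotype labels, and KO below means a library labelled KO. Among the other PRC2 core genes, Suz12 was at 35.6 and 40.7 FPKM in WT and KO iNKT and at 23.2 in both CD44hi libraries. Eed was at 35.2 FPKM in both iNKT libraries, 28.4 in WT CD44hi and 29.1 in KO CD44hi. Ezh1, the other catalytic subunit, was 1.31-fold lower in KO iNKT (interval 1.17 to 1.48; 21.7 to 16.6 FPKM) and 1.12-fold lower in KO CD44hi (24.0 to 21.5 FPKM). None of 12 measured PRC2 subunits differed by 2-fold between genotypes in either cell type, with medians of 0.15 in iNKT and 0.02 in CD44hi. Phf1 lay just inside the rule in iNKT (78.2 to 38.6 FPKM). Of 55 developmental regulators known as PRC2 targets, 0 were measured in the iNKT pair. In the CD44hi pair 3 were measured, Hoxa7 (0.270 in WT, 1.20 in KO), Hoxa5 (0.627, 1.35) and Hoxb4 (1.09, 1.71 FPKM). All 3 were higher in KO, by plain ratios of 4.43, 2.15 and 1.57, but within 2-fold on the log2(FPKM + 1) scale, which shrinks such low values. Cdkn2a, a cell cycle inhibitor silenced by PRC2 in many cells, was at 0.899 FPKM in WT iNKT, listed at 0 in KO iNKT, and at 0.362 and 1.47 in WT and KO CD44hi.

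The CD44hi libraries carried markers of cells other than T cells, and these differed between genotypes. Cd74, the invariant chain of MHC class II, was at 14.4 and 33.1 FPKM in WT and KO iNKT but at 1337 and 2171 in WT and KO CD44hi. Siglech, a plasmacytoid dendritic cell marker, was listed at 0 in both iNKT libraries and was at 11.1 and 75.7 FPKM in WT and KO CD44hi. Tyrobp, a myeloid and NK cell adaptor, was at 6.95, 1.98, 121 and 305 FPKM in WT iNKT, KO iNKT, WT CD44hi and KO CD44hi. Haemoglobin genes took 0.00623%, 0.00653%, 0.0530% and 0.244% of the summed FPKM in the same order. The Y-linked genes Eif2s3y (22.7 FPKM) and Ddx3y (11.5 FPKM) were found in WT CD44hi alone, beside 46.8 FPKM of Xist, which is transcribed from the inactive X chromosome of female cells. Xist was at 55.3 in WT iNKT, 76.8 in KO iNKT and 80.0 in KO CD44hi. The sex of the donor cells therefore differed between WT CD44hi and the other 3 libraries.

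**Figure D1:**
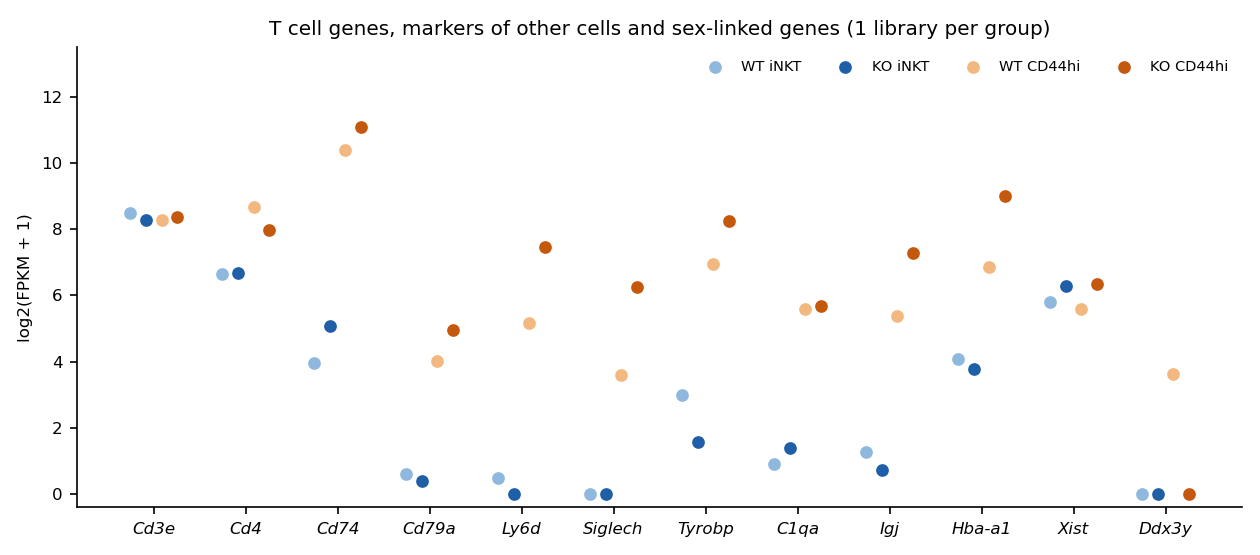
Expression, as log2(FPKM + 1), of 2 T cell genes (Cd3e, Cd4), of markers of B cells, plasmacytoid dendritic cells, myeloid cells, plasma cells and red cells, and of the sex-linked genes Xist and Ddx3y; each point is 1 library. Markers of other cells sit higher in both CD44hi libraries than in the iNKT libraries, with Siglech at 11.1 and 75.7 FPKM in WT and KO CD44hi, and Ddx3y (11.5 FPKM) stands out in WT CD44hi alone.

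KO iNKT was compared with WT iNKT to ask which genes differ between the genotypes in this lineage. Type 1 effector genes were lower in KO iNKT, and genes of follicular helper T (Tfh) cells and proliferation were higher. Tbx21, which encodes T-bet, the master regulator of type 1 responses (chromosome 11, 97098071 to 97115331), was 3.60-fold lower (interval 3.13 to 4.17; 70.4 to 19.5 FPKM), and Ifng, the type 1 cytokine, 8.67-fold lower (6.87 to 11.1; 112 to 12.9 FPKM). Zbtb16, which encodes PLZF, the transcription factor that directs iNKT development (chromosome 9, 48654297 to 48836222), was 2.24-fold higher (2.05 to 2.45; 28.2 to 63.1 FPKM). Tcf7, a factor of progenitor and memory T cells (chromosome 11, 52252371 to 52283014), was 3.51-fold higher (3.34 to 3.68; 159 to 558 FPKM). In all, 658 of 10820 measured genes were at least 2-fold higher and 362 at least 2-fold lower.

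The type 1 list had 13 of 17 measured members lower and 1 higher, with a median log2 difference of -1.80 (percentile 0 of matched random lists). Besides Ifng, Nkg7, a granule protein, went from 437 to 73.5 FPKM, and Il12rb2, a subunit of the IL-12 receptor, from 29.1 to 4.51. Eomes was listed at 0 in WT iNKT and was at 3.90 in KO iNKT. The type 17 list had 7 of 13 measured members lower and 1 higher (median -1.12, percentile 0). Among them, Tmem176b went from 10.8 to 1.87 FPKM. The type 2 list had 4 of 11 higher and 1 lower (median 0.42, percentile 98.2). Il4 was at 52.3 and 118 FPKM, and Ccr4, a receptor found on type 2 cells, at 10.8 and 46.2. Areg was at 0.195 and 1.98, and Ptgir at 2.29 and 0.401. Gata3, the type 2 master regulator, was 1.72-fold lower (1.54 to 1.92; 53.5 to 31.1 FPKM).

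Among 15 measured Tfh genes, 10 were higher and 0 lower in KO iNKT (median 1.33, percentile 100). Pdcd1, which encodes the inhibitory receptor PD-1, was 18.3-fold higher (14.9 to 22.8; 10.2 to 187 FPKM). Tox2 went from 0.658 to 25.6 FPKM, Il21 from 0.135 to 13.3 and Angptl2 from 0.0597 to 21.6. Bcl6, the Tfh master regulator, was 1.93-fold higher (1.51 to 2.51; 5.59 to 10.8 FPKM) and did not pass the 2-fold rule. Of 12 measured inhibitory receptors and exhaustion genes, 6 were higher and 1 lower (median 1.61, percentile 100), with log2 differences below 0 in 5, and those higher included Cd200 (2.44 to 40.8 FPKM), Lag3 (0.538 to 11.3) and Nr4a2 (log2 difference 3.30). The proliferation list had 11 of 30 members higher and 0 lower (median 0.85, percentile 100). Uhrf1, a DNA methylation maintenance factor, went from 6.14 to 25.6 FPKM, Ccne1 from 4.97 to 13.4 and Cdc20 from 4.23 to 10.9. Of 5 measured CDK inhibitors, Cdkn1c was higher (0.228 to 1.47), while Cdkn1b was at 64.8 and 36.3 FPKM (list median -0.04, percentile 33.6).

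Cytotoxic genes went in both directions in KO iNKT: of 12 measured granule genes 5 were lower and 1 higher (median -0.75, percentile 0). Gzma, which encodes granzyme A, was 51.7-fold higher (27.3 to 126; 1.72 to 89.0 FPKM), while Prf1 (perforin) went from 11.6 to 1.45 and Gzmb from 4.63 to 0.443. NK cell receptors likewise split, with 6 of 20 higher and 5 lower. Klra1 went from 10.7 to 107 FPKM, Klrb1a from 6.66 to 29.9 and Klra3 from 10.1 to 37.5, and Klre1 from 25.7 to 5.81. The receptor median of 0.57 (percentile 100) turned to -0.78 among genes at 5 FPKM or more, and Klra genes share near-identical sequence, so single members of that family are uncertain. Shared iNKT genes showed the same split, with 4 of 13 higher and 3 lower (median -0.29, percentile 0.66). Cxcr6, a homing receptor of iNKT cells, went from 468 to 94.6 FPKM and Il2rb, the IL-15 receptor beta chain, from 814 to 198, whereas Egr2, which acts upstream of Zbtb16, went from 1.96 to 14.6 and Hivep3 from 0.702 to 5.91.

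The 10 largest positive differences in KO iNKT were in Rln3, Ptpn5, Atp6v0c-ps2, Gzma, Epha3, Nrgn, Angptl2, Eng, Pdcd1 and Tox2. Rln3, a relaxin peptide, went from 2.86 to 166 FPKM, Ptpn5, a tyrosine phosphatase, from 0.892 to 71.4, Nrgn from 6.75 to 172, Epha3, an ephrin receptor, from 0.0513 to 22.4, and Eng, the TGF beta co-receptor endoglin, from 2.58 to 71.9. Atp6v0c-ps2 is a pseudogene (0.0468 to 33.7 FPKM) that can take reads from its parent gene. The 10 largest negative differences were in Ndufs5, Serpina3f, Socs2, Serpina3g, Sytl3, Anxa1, Clec2i, Ifng, S100a4 and Klra13-ps. Serpina3f, a serine protease inhibitor, went from 77.6 to 2.74 FPKM, Serpina3g from 76.1 to 4.51, Socs2, a suppressor of cytokine signalling, from 27.3 to 0.444, Sytl3 from 41.3 to 3.35, Anxa1 from 15.0 to 0.752, Clec2i from 49.8 to 5.12 and S100a4 from 76.1 to 8.50. Ndufs5 was at 22.2 and 0.00789 FPKM; the second value is below what 1 fragment is worth and is uncertain, as is the pseudogene Klra13-ps (6.57 FPKM in WT).

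**Figure D2:**
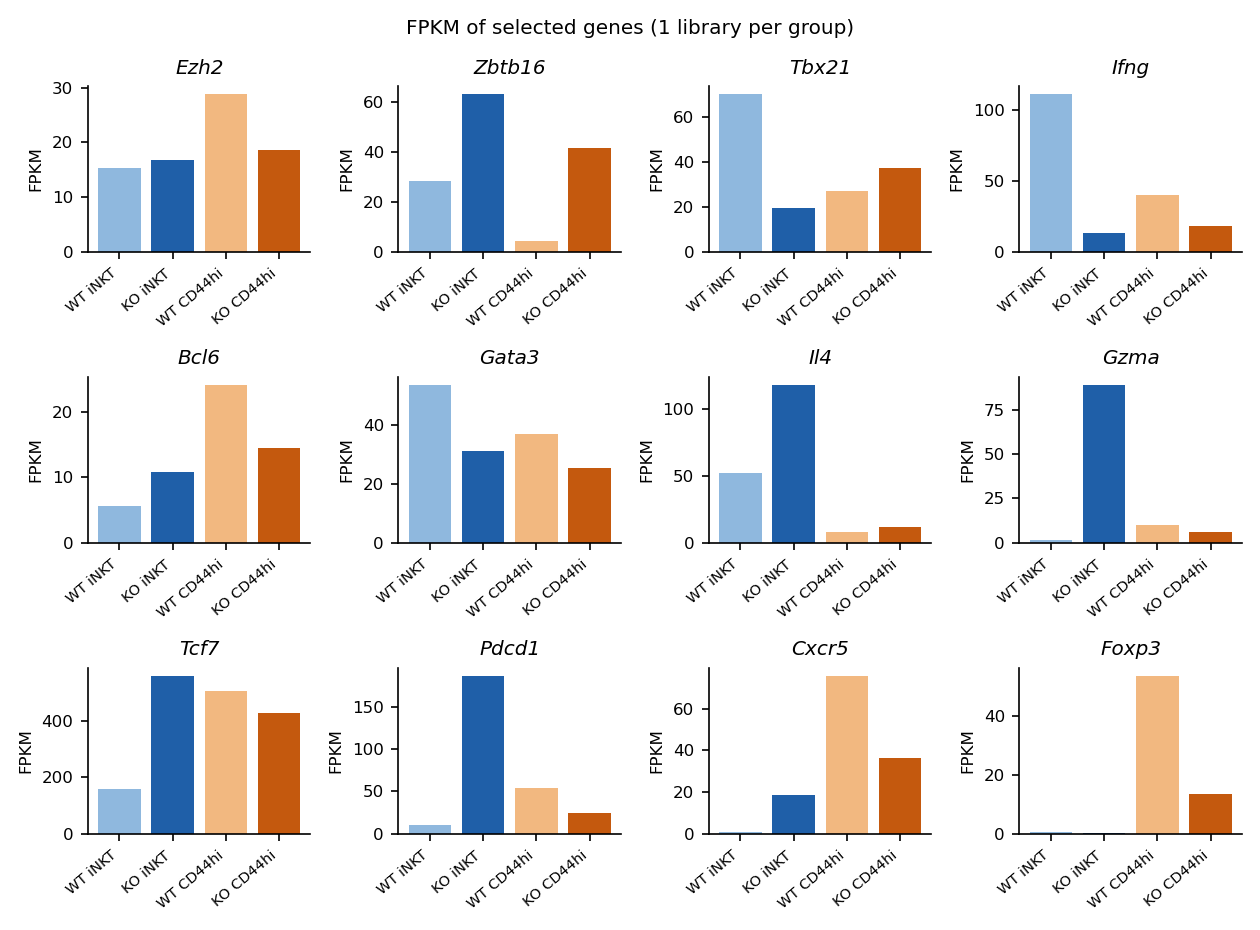
FPKM of 12 genes in each of the 4 libraries; each bar is 1 library and starts at 0, and each panel has its own axis. Tbx21 and Ifng are lower in KO iNKT than in WT iNKT (19.5 against 70.4 FPKM for Tbx21), Tcf7 and Pdcd1 are higher, and Zbtb16 is higher in both KO libraries than in their WT pairs.

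Interferon stimulated genes had 2 of 30 lower and 0 higher (median -0.35, percentile 0), with Ifi44 at 2.79 and 0.199 FPKM and Gbp6 at 51.5 and 23.3. Trafficking receptors had 5 of 19 higher, led by Cxcr5 (0.963 to 18.8 FPKM) and Itga4 (10.9 to 49.4), and 7 lower, among them Ccr9 (41.0 to 8.81), for a median of -0.42 (percentile 0.01). Cytokines had 7 of 21 higher and 5 lower (median 0.15, percentile 76.1); Tnfsf11, which encodes RANKL, went from 8.10 to 61.9 FPKM and Ccl5 from 925 to 204. Treg genes had 5 of 15 higher and 2 lower (median -0.13, percentile 7.56), with Folr4 at 124 and 461, Nrp1 at 8.84 and 37.6 and Prdm1 at 12.4 and 1.74, while Foxp3 was at 0.446 and 0.115 FPKM. Naive and homing genes had 5 of 17 higher and 3 lower (median -0.05, percentile 18.4), with Actn1 at 4.13 and 18.7. T cell identity genes had 1 of 18 higher and 3 lower (median -0.12, percentile 5.70): Thy1 went from 449 to 82.7 FPKM and Cd2 from 166 to 63.3. Immediate early genes had 4 of 24 higher, such as Egr3 (5.43 to 25.3), and 2 lower, such as Jun (69.0 to 18.0), with a median of 0.09 (percentile 73.9). Apoptosis genes had 2 of 24 higher and 4 lower (median -0.22, percentile 0.21); Pmaip1 went from 0.395 to 10.2 and Bcl2 from 23.6 to 6.31. TGF beta, Notch and Wnt genes had 4 of 18 higher, including Fzd6 (0.599 to 9.38), and 2 lower, Smad7 (log2 difference -2.11) and Dtx1 (120.2 to 29.6), for a median of 0.06 (percentile 50.1). Heat shock genes had 1 of 15 higher, Hsp90ab1 (391 to 927), with a median of 0.25 (percentile 97.9). PRC1 and H3K27 demethylase genes had 1 of 15 lower, Pcgf1 (7.80 to 2.14), with a median of 0.10 (percentile 74.4).

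Housekeeping lists stayed within 2-fold in the iNKT pair for every measured member: 36 ribosomal protein genes (median 0.15, percentile 97.7), 28 oxidative phosphorylation genes (0.07, percentile 72.6) and 18 glycolysis genes (0.08, percentile 69.4). In the lists of markers of other cells, only 4 of 18 B cell markers were measured (median 0.70, percentile 95.2), of which Cd74 was higher. Myeloid markers had 4 of 13 lower and 0 higher (median -0.57, percentile 0.03), led by Ccr2 (106 to 27.8 FPKM), which T cells also express, and C1qc (2.96 to 0.421). Plasma cell markers had 1 of 7 lower, Prdm1 (median 0.12, percentile 52.0), and NK cell and ILC1 markers 3 of 11 higher and 5 lower (median -0.93, percentile 0). The 4 measured CD8 T cell markers were the type 1 genes Nkg7, Ccl5 and Eomes and the NK cell receptor gene Klrd1 (median -1.92, percentile 0). The gamma delta markers Sox13 (0.873 to 6.30 FPKM) and Cd163l1 (6.91 to 2.09) went in opposite directions. All 3 measured stromal markers were higher, among them Pecam1 (22.1 to 52.4), and neither measured red cell gene passed the rule, with Hba-a1 at 15.8 and 12.6. Counting alone, simulated with no difference at the estimated depths, gave 10.6 genes higher and 9.20 lower, against 596 and 322 observed among genes with a known length.

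KO CD44hi was compared with WT CD44hi to ask the same question in CD44hi CD4+ T cells. NK cell receptors and single iNKT genes, such as Zbtb16, were higher in KO CD44hi, and genes of regulatory T (Treg) and Tfh cells were lower. Zbtb16 was 9.64-fold higher (8.71 to 10.7; 4.30 to 41.4 FPKM), and Il17rb, the IL-25 receptor subunit carried by type 2 iNKT cells, 10.7-fold higher (9.51 to 12.2; 7.55 to 80.9 FPKM). Foxp3, the Treg master regulator (chromosome X, 7573644 to 7595245), was 4.01-fold lower (3.76 to 4.27; 53.8 to 13.4 FPKM). In all, 277 of 11357 measured genes were at least 2-fold higher and 129 at least 2-fold lower. Among genes at 5 FPKM or more in an iNKT library, which leaves out most genes of B, myeloid and red cells, 120 were higher and 44 lower. This setting also leaves out T cell genes low in both iNKT libraries, such as Foxp3 (0.446 and 0.115 FPKM in WT and KO iNKT). The smaller counts therefore do not only reflect the removal of other cells.

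The NK cell receptor list had 10 of 19 measured members higher and 1 lower (median 1.15, percentile 100). Klra3 went from 0.925 to 14.3 FPKM, Klra1 from 0.610 to 8.16 and Cd160 from 13.2 to 54.5, whereas Klrg1 had a log2 difference of -2.05. As in the iNKT pair, single members of the Klra family are uncertain. Of 13 iNKT lineage genes 3 were higher, Zbtb16, Klrb1c (which encodes NK1.1; 14.9 to 58.5) and Plac8 (42.0 to 146), and 1 was lower, Slamf1 (16.2 to 7.08), so that the list median stayed at -0.29 (percentile 0.02). Type 1 genes were balanced (1 higher, 1 lower of 19; median 0.09, percentile 87.2). Ifng had a log2 difference of -1.12 and Il18rap went from 13.3 to 29.7 FPKM, and Tbx21 was at 27.3 and 37.3. Type 17 genes had 3 of 18 lower and 0 higher (median -0.45, percentile 0): among these, Il17re went from 6.47 to 1.67 and Ccr6 from 25.7 to 10.5. Of 14 type 2 genes, Il17rb was higher and 3 were lower, Il10 (5.86 to 0.394), Areg (2.58 to 0.278) and Ccr8 (6.67 to 1.91), for a median of -0.55 (percentile 0). Gata3 was at 36.8 and 25.3. Granule genes had Ctsw higher (58.6 to 154) and Gzmk (21.3 to 4.64) and Gzmb (9.22 to 2.87) lower (median -0.02, percentile 28.8 of 13 measured).

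Treg genes were lower as a group in KO CD44hi, with 12 of 19 lower and 0 higher (median -1.33, percentile 0). Lrrc32 (GARP) went from 11.7 to 2.02 FPKM, Tigit from 80.1 to 20.5 and Ctla4 from 123 to 33.8. Tfh genes had 6 of 17 lower and 0 higher (median -0.70, percentile 0): Angptl2 went from 27.7 to 2.68, Il21 from 15.0 to 2.34 and Sostdc1 from 20.5 to 4.37, with Bcl6 at 24.1 and 14.5. Inhibitory receptors had 3 of 14 lower and 1 higher (median -0.58, percentile 0), Pdcd1 going from 53.6 to 24.0. Trafficking receptors had 5 of 24 lower and 1 higher (median -0.39, percentile 0), the higher one being Ccr9 (7.91 to 41.0) and the lower ones including Itgae (6.25 to 0.949). Cytokines had 6 of 27 lower and 0 higher (median -0.28, percentile 0.01), including Csf1 (6.44 to 1.86). T cell identity genes all stayed within 2-fold (median -0.33 of 18, percentile 0), with Cd4 at 405 and 252 FPKM and Cd2 at 394 and 217; Tcf7 was at 505 and 429. Immediate early genes had 2 of 24 lower, Tnfaip3 (101 to 48.9) and Cd69 (70.1 to 34.0), with a median of -0.45 (percentile 0).

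Markers of other cells differed beside these groups in the CD44hi pair. B cell markers had 2 of 17 higher and 0 lower (median 0.63, percentile 100), with Ly6d at 34.7 and 174 FPKM and Blnk at 2.77 and 10.4. Myeloid markers had 4 of 21 higher and 0 lower (median 0.33, percentile 100), including Mpeg1 (18.2 to 75.8) and Ly86 (28.5 to 64.5). Of 7 red cell and platelet markers 6 were higher (median 1.64, percentile 100), with Hba-a1 at 115 and 509. Plasma cell markers had Igj higher (40.3 to 154) and Prdm1 lower (6.27 to 2.10), with a median of 0.49 (percentile 99.9) that turned to -0.21 among genes at 5 FPKM or more in an iNKT library. NK cell and ILC1 markers had 1 of 11 higher, Tyrobp, and 1 lower, Klrg1; their median of -0.26 (percentile 0.33) turned to 0.42 among genes at 5 FPKM or more. Gamma delta markers had Sox13 higher (0.0947 to 6.30; median 0.74 of 4, percentile 99.3), and CD8 T cell markers had 1 of 8 lower, Gzmk (median 0.20, percentile 94.8). Stromal markers had Kdr higher (0.530 to 2.09) and Igfbp7 lower (3.21 to 0.949), with a median of 0.43 (percentile 93.8). The 4 Y-linked genes were lower or listed at 0 in KO CD44hi (Kdm5d 4.16 in WT, Uty 1.93), which sets the sex-linked median to -2.37 (percentile 0).

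The 10 largest positive differences in KO CD44hi were in Eng (70.3-fold, 50.8 to 102; 0.553 to 38.9 FPKM), Klra23 (12.2 in KO), Il17rb, Zbtb16, Klra3, Atp6v0d2 (3.15 to 30.4), Clec10a (1.34 to 16.2), Klk1 (6.51 to 53.7), Chdh (3.24 to 27.6) and Sox13. Klra23 was at 2.12e-06 FPKM in WT CD44hi, which is below what 1 fragment is worth, and is uncertain. Clec10a is a lectin of dendritic cells and macrophages. The 10 largest negative differences were in Eif2s3y, Ddx3y, Angptl2, Dapl1 (26.6 to 3.10), Zbtb32 (11.4 to 1.31), Gpm6b (26.3 to 4.36), Il10, Il21, Lrrc32 and Klrg1. Remaining lists had few members past the rule. Naive and homing genes had 2 of 18 higher, among them Ly6c2 (48.9 to 161), and 2 lower, among them Igfbp4 (log2 difference -1.61), with a median of -0.20 (percentile 0.14). Interferon genes had Bst2 higher (64.1 to 195; median 0.18 of 30, percentile 100), a gene that plasmacytoid dendritic cells also express. TGF beta, Notch and Wnt genes had Fzd6 (0.406 to 4.96) and Hes1 (2.34-fold) higher (median -0.18 of 18, percentile 0.14), and PRC1 genes had Y-linked Uty lower (median -0.15 of 16, percentile 1.38). Within 2-fold for every measured member were 30 proliferation genes (median -0.04, percentile 18.9), 24 apoptosis genes (0.03, percentile 62.6), 6 CDK inhibitors (-0.01, percentile 31.1), 36 ribosomal protein genes (0.23, percentile 100), 28 oxidative phosphorylation genes (0.09, percentile 91.1), 20 glycolysis genes (-0.03, percentile 20.7) and 18 heat shock genes (0.09, percentile 84.5).

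**Figure D3:**
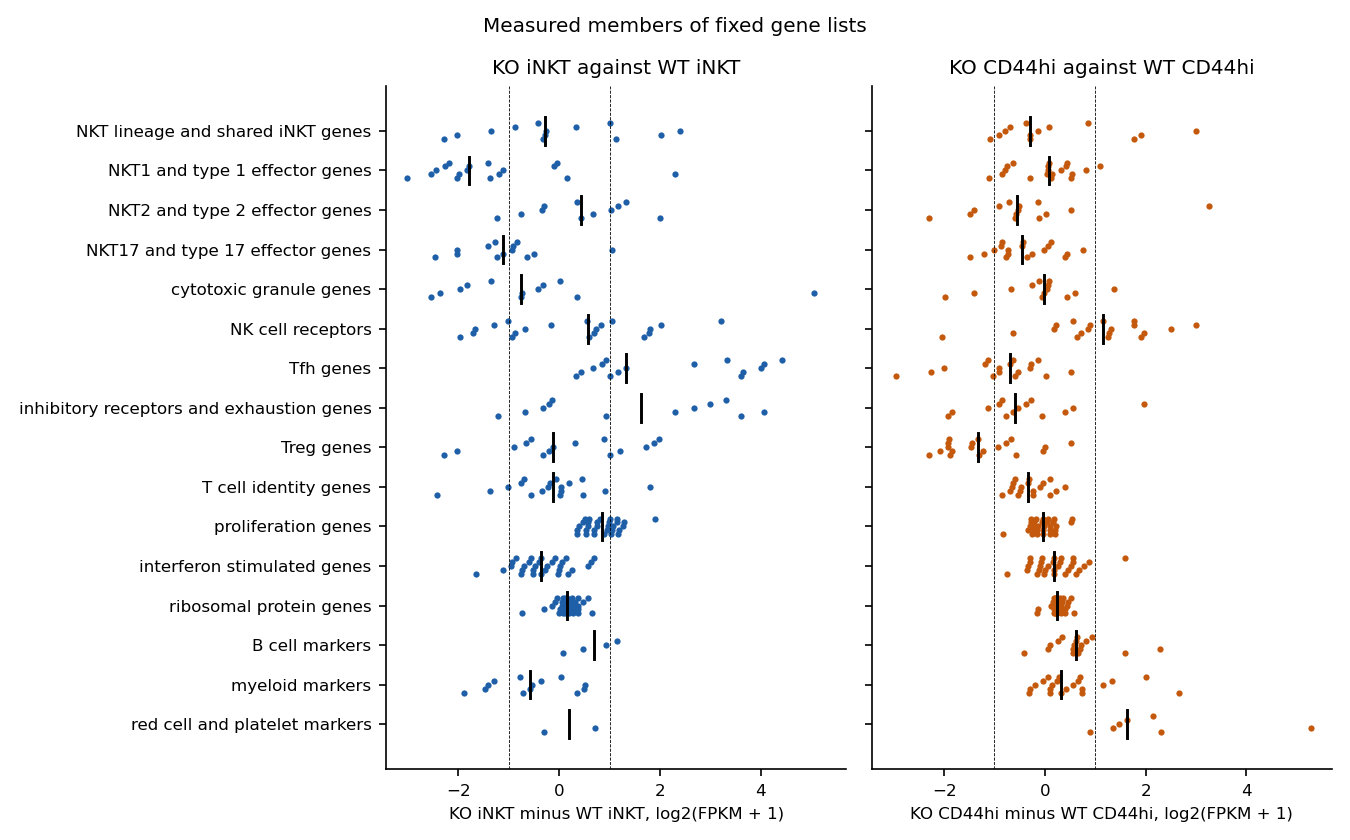
Difference of log2(FPKM + 1) between KO and WT for each measured member of 16 gene lists, in the iNKT pair (left) and the CD44hi pair (right); points are genes, black bars list medians and dashed lines mark 2-fold. Tfh genes lie above 0 in the iNKT pair (median 1.33) and mostly below it in the CD44hi pair (median -0.70), and type 1 genes have a median of -1.80 in the iNKT pair and of 0.09 in the CD44hi pair, a difference that was not tested.

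The 2 genotype effects were set side by side to see whether iNKT and CD44hi cells differed from WT in the same genes. Among 10456 genes measured in both pairs, 67 were higher in both KO libraries, where independent lists of those sizes would share 9.19, and 18 were lower in both, against 2.52. In opposite directions, 27 genes were higher in KO iNKT and lower in KO CD44hi (4.30 from independent lists) and 24 the reverse (5.40). The correlation of the 2 effects across genes was weak (Pearson r 0.0970, Spearman rho 0.0905). Zbtb16, Eng, Epha3 (0.362 to 7.39 FPKM in CD44hi), Klra1, Klra3 and Atp6v0d2 (7.66 and 39.3 FPKM in WT and KO iNKT) were among those higher in both. Ifng, Gzmb, Prdm1, Serpina3f and Socs2 (12.4 to 4.60 FPKM in CD44hi) were lower in both. The largest differences between the effects were in Angptl2, Il21, Ptpn5, Gzma and Pdcd1, all relatively higher in KO iNKT, with 7.38, 5.91, 5.87, 5.71 and 5.19 on the log2 scale. At the other end stood Ndufs5 (-4.93), Ccr9 (-4.33), Ly6g5b (-3.82), Aqp9 (-3.75) and Il17rb (-3.60), which in iNKT was at 160 FPKM in WT and 126 in KO. None of these differences was tested. Since markers of other cells were higher in KO CD44hi, a rise there, such as that of Ccr9, may come from those cells rather than from CD4+ T cells.

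**Figure D4:**
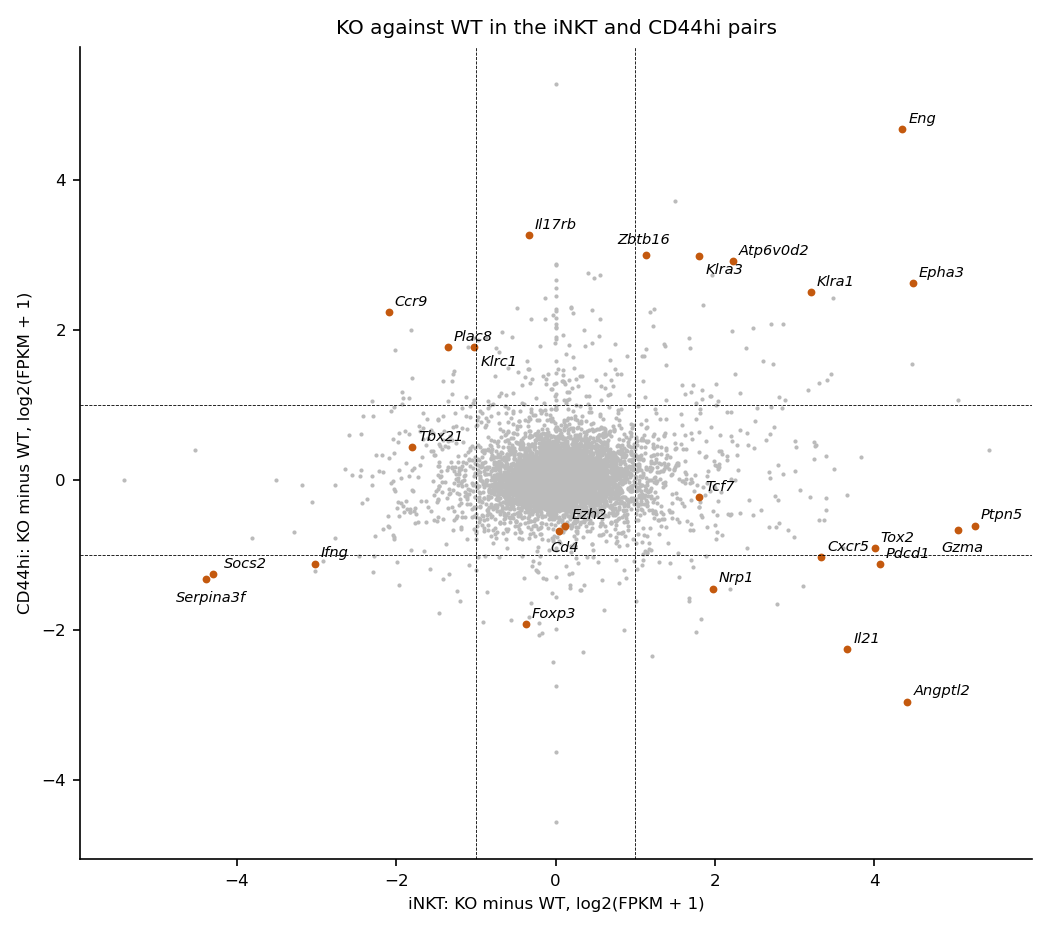
Difference of log2(FPKM + 1) between KO and WT in the iNKT pair (horizontal axis) against the CD44hi pair (vertical axis) for genes at 5 FPKM or more in any library; each point is a gene and dashed lines mark 2-fold. Eng and Zbtb16 are higher in both pairs, Angptl2, Il21 and Pdcd1 are higher in KO iNKT and lower in KO CD44hi, and Ccr9 and Plac8 the reverse (r 0.0970 across the 10456 genes measured in both pairs). Markers of other cells were also higher in KO CD44hi, so rises there, as in Ccr9 and Plac8, may come from those cells.

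WT iNKT was compared with WT CD44hi to describe what sets the cell types apart in WT mice. WT iNKT was higher in NK cell receptors and type 1 genes and lower in Treg, Tfh and inhibitory receptor genes and in markers of B and myeloid cells. Zbtb16 was 6.56-fold higher (5.80 to 7.42), Il17rb 21.2-fold higher (18.7 to 24.2), Klrb1c 11.9-fold higher (10.9 to 13.0; 14.9 to 177 FPKM) and Tbx21 2.58-fold higher (2.36 to 2.82). Foxp3 was 121-fold lower (62.4 to 259; 53.8 to 0.446 FPKM) and Cxcr5 78.8-fold lower (45.2 to 139; 75.9 to 0.963 FPKM). Tcf7 was 3.17-fold lower (3.03 to 3.32) and Bcl6 4.31-fold lower (3.51 to 5.37). In all, 411 of 11222 measured genes were at least 2-fold higher and 1226 lower. Among genes at 5 FPKM or more in an iNKT library, 358 were lower and nearly as many were higher. This filter takes out genes low in both iNKT libraries, even where CD44hi is high, so it removes lower genes by construction. The near balance is thus no sign that the excess is limited to poorly measured genes. With the filter at 5 FPKM, which does not select on the iNKT libraries, 694 genes were lower and fewer were higher, so the excess stayed.

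NK cell receptors had 13 of 20 members higher and 4 lower (median 2.09, percentile 100), including Klrc2 (4.92 to 53.5 FPKM) and Klrd1 (23.9 to 182). Type 1 genes had 10 of 19 higher and 4 lower (median 1.34, percentile 100), with Nkg7 going from 78.7 to 437 and the chemokine gene Ccl3 from 13.0 to 0.660. iNKT lineage genes had 5 of 13 higher and 3 lower (median 0.41, percentile 99.5), granule genes 6 of 13 higher and 2 lower (0.48, percentile 99.8) and interferon genes 7 of 30 higher and 0 lower (0.64, percentile 100), such as Ifi47 (62.8 to 222). Treg genes had 13 of 19 lower and 0 higher (median -1.52, percentile 0), Tfh genes 11 of 17 lower and 1 higher (-2.28, percentile 0) and inhibitory receptors 10 of 14 lower and 1 higher (-2.30, percentile 0), with Tigit at 80.1 and 1.78 and Lag3 at 38.7 and 0.538. Type 17 genes had 12 of 18 lower and 1 higher (median -1.14, percentile 0.01), led by Ccr6 (25.7 to 0.190). A part of other cells in the CD44hi values of this list was not tested. Il4 was higher (8.03 to 52.3) in a type 2 list with 2 of 15 higher and 6 lower, whose median of -0.88 turned to 0.53 among genes at 5 FPKM or more in an iNKT library. T cell identity genes had 5 of 18 lower, including Cd4 (405 to 98.8), with a median of -0.16 (percentile 7.39).

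All 17 measured B cell markers and 20 of 23 myeloid markers were lower in WT iNKT (medians -3.42 and -3.28, percentile 0 for both). Of the 10 largest negative differences, H2-Ab1 (605 to 2.54 FPKM), H2-Aa (493 to 2.01), H2-Eb1 (331 to 1.32), Cd74, H2-DMb2 (61.1 to 0.333) and H2-DMb1 (36.8 to 0.179) are MHC class II pathway genes, and Hbb-b1 (33.4 FPKM in WT CD44hi) is a haemoglobin gene. The others were Cxcr5, Foxp3 and the pseudogene Atp6v0c-ps2. The 10 largest positive differences were in Eif3j, Il17rb, Klrb1c, Klrc2, Klra23, Padi2 (9.38 to 86.3), Aqp9 (3.25 to 32.1), Klrc3 (1.57 to 18.8), Qpct (2.53 to 25.5) and Klrd1. Eif3j (26.4 FPKM in WT iNKT) has a near-identical copy and is uncertain. Klra23 (8.04 FPKM in WT iNKT) is uncertain too, since its 2.12e-06 FPKM in WT CD44hi is below what 1 fragment is worth. Ribosomal protein genes had a median of 0.40 (percentile 100), with 1 of 36 higher and 2 lower. CD8 T cell markers had 3 of 8 higher and 5 lower, and their median of -1.36 turned to 1.59 among genes at 5 FPKM or more.

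KO iNKT was compared with KO CD44hi to see which of these differences are found in KO mice. KO iNKT was higher in Tfh and proliferation genes and lower in type 17 genes and in markers of B, myeloid and red cells. Il4 was 9.94-fold higher (8.60 to 11.5; 11.9 to 118 FPKM), Gzma 15.0-fold higher (12.5 to 18.3), Ptpn5 24.2-fold higher (21.2 to 27.9) and Pdcd1 went from 24.0 to 187 FPKM. Zbtb16 was 1.52-fold higher (1.44 to 1.61) and did not pass the 2-fold rule, and Tbx21 was 1.91-fold lower (1.68 to 2.19). Foxp3 was 117-fold lower (39.6 to 1186), on an estimated 2.45 fragments in KO iNKT. In all, 347 of 11474 measured genes were at least 2-fold higher and 1041 lower. Among genes at 5 FPKM or more in an iNKT library, 243 were lower and about as many were higher. That filter takes out genes low in both iNKT libraries, even where CD44hi is high, so it removes lower genes by construction. The near balance therefore does not show that the excess is limited to poorly measured genes. The filter at 5 FPKM, which does not select on the iNKT libraries, left 577 genes lower and fewer higher, so the excess stayed.

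Tfh genes had 7 of 16 higher and 2 lower (median 0.97, percentile 100), proliferation genes 9 of 30 higher and 0 lower (0.75, percentile 100) and type 2 genes 4 of 11 higher and 0 lower (0.64, percentile 100), among them Icos (77.5 to 218 FPKM) and Il13 (0.434 to 3.40). Type 17 genes had 12 of 15 lower and 0 higher (median -1.34, percentile 0), with Tmem176b at 75.5 and 1.87. Whether other cells in the CD44hi sort add to the CD44hi values of this list was not tested. Type 1 genes had 3 of 19 lower and 0 higher (median -0.45, percentile 0.01), among them Ccl3 (17.7 to 0.611) and Stat4 (33.5 to 9.03). NK cell receptors had 6 of 21 higher, including Klra1 (8.16 to 107) and Klrb1a (2.81 to 29.9), and 2 lower (median 0.21, percentile 96.6). Treg genes had 7 of 17 lower and 3 higher, and their median of -0.45 turned to 0.02 among genes at 5 FPKM or more in an iNKT library. In the same way the median of inhibitory receptors (5 of 14 lower, 3 higher) went from -0.50 to 0.85. B cell markers (17 of 17 lower, median -3.51), myeloid markers (20 of 23 lower, -3.48) and red cell markers (7 of 8 lower, -3.03) all lay at percentile 0. The other genes among the 10 largest positive differences were Vdr (1.60 to 28.0), Nrgn, Fgf18 (0.179 to 11.6), Prg4 (4.94 to 51.4) and Nr4a2 (log2 difference 3.01). The 10 largest negative differences were in H2-Ab1, Ly6d, H2-Eb1, Hbb-b1, H2-Aa, Tyrobp, Igj, Ctsh, Siglech and Pld4, which are genes of B, myeloid, plasma, plasmacytoid dendritic or red cells. Of the cell type differences, 660 genes were lower in iNKT in both genotypes (95.8 from independent lists; 337 with a filter at 5 FPKM and 96 among genes at 5 FPKM or more in an iNKT library) and 67 higher in both (9.72), and the differences correlated across 10975 genes with r 0.654.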

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

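The tests of added cells and of dilution were chosen after the result was seen, and those of depth and counting error before. Genes of the lists or the naming rule that passed 2-fold in both genotype pairs in opposite directions stand out, since the pairs differ in direction. With 1 library per group that difference was not tested. Higher in KO iNKT and lower in KO CD44hi were Angptl2 (difference of the log2 effects 7.38), Il21 (5.91), Pdcd1 (5.19), Cxcr5 (4.37), Gpm6b (3.56), Nrp1 (3.42), Igfbp4 (3.28), Igfbp7 (2.91), Areg (2.81) and Itgb1 (2.21). Igfbp7 and Areg stayed below 5 FPKM in every library, and Gpm6b did in both iNKT libraries, so their iNKT differences rest on low values. Lower in KO iNKT and higher in KO CD44hi were Ccr9 (-4.33), Ly6g5b (-3.82), Aqp9 (-3.75), Plac8 (-3.13), Klrc1 (-2.80), Tyrobp (-2.74), Klrc2 (-2.61) and Il18rap (-2.22). Markers of other cells were higher in KO CD44hi. Tyrobp was at 121 and 305 FPKM in WT and KO CD44hi, against 6.95 and 1.98 in WT and KO iNKT. Its change in CD44hi, and perhaps that of others here, may therefore come from those cells.

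NK cell receptors were higher in KO CD44hi than in WT CD44hi (10 of 19), as were 3 of 13 iNKT lineage genes (Zbtb16, Klrb1c and Plac8), although the median of that lineage list was -0.29; markers of other cells were higher too (Tyrobp 121 to 305 FPKM, Siglech 11.1 to 75.7), while the median of NK cell and ILC1 markers was -0.26 (0.42 with a filter at 5 FPKM). The difference in depth between these libraries is argued against, since thinning KO CD44hi to the WT depth left 98.8% of these 12 called genes past 2-fold. Cells like the KO iNKT library would move all their abundant genes by the same share of the way. The lower quartile of the shares over 43 genes was instead 0.176 of the upper, with Il4 at 3.52% and Zbtb16 at 63.2%. Plac8 was at 2.43 times (counting interval 2.20 to 2.69) its level in KO iNKT itself. Other cells in the sort may add to Plac8, so that value does not count against iNKT cells being present beside them. Cells like the WT iNKT library would not alone give values above their own level. In KO CD44hi, Zbtb16 was at 1.47 times (1.36 to 1.59) its level in WT iNKT, and Klrb1b at 2.17 times (1.59 to 2.98). Klra3 was at 1.42 times (1.09 to 1.90) but is uncertain as a single Klra gene. These intervals cover counting error only, so a difference between mice or sorts is not excluded. The quartile value of 0.263 over 44 genes, Zbtb16 among them, lay between the bounds set. Cells like WT iNKT therefore cannot be told apart from a gain in CD4+ T cells, and the sort names no removal of tetramer-binding cells. Of 2 other forms of this test, tried after the first gave its values and resting on genes picked for being higher, the share of all genes over that of the called genes was 0.327 (KO profile) and 0.203 (WT), and for the 10 most abundant genes 0.128 and 0.182 (Il2rb at -12.0% for WT), so the forms disagree for each profile and iNKT cells of a mixed or other profile stay open, as does a part played by the other cells in the sort.

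Type 1 genes were lower and Tfh genes higher in KO iNKT than in WT iNKT. Counting error in these shallow libraries gave 2.15% of the observed number of genes past 2-fold. Cells with the whole profile of the WT CD44hi library in the KO iNKT sort would bring their other abundant genes. The median share of the way to WT CD44hi over 99 such genes was 0.0182 of that over 7 Tfh genes. For 4 Treg genes the median share was -0.957%. The 99 genes take in MHC class II genes such as H2-Ab1, which mark other cells in the CD44hi sort. These values therefore argue against that whole profile, but not against CD4+ T cells alone, such as Tfh cells, in the KO iNKT sort. A candidate explanation is a change in the mix of iNKT subsets or in gene expression within them in KO mice, which these libraries do not separate. A difference between single mice or sorts, including sorted Tfh-like iNKT cells present in 1 pool alone, was not tested.

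Treg and Tfh genes were lower in KO CD44hi than in WT CD44hi, while markers of B, myeloid and red cells were higher. Fewer T cells of all kinds would lower T cell identity genes as much, but over 19 measured Treg genes the median of -1.33 lay 1.01 below the identity median of -0.33, and 13 of them were lower than the lowest identity gene (-0.86). Of 17 Tfh genes, 8 were lower than it too, down to -2.96 (Angptl2), which fewer T cells alone would not give, but the Tfh median of -0.70 lay 0.373 below, between the bounds set, so for the other 7 that were lower fewer T cells cannot be told apart from lower Tfh expression. Fewer Treg cells, or lower expression within them, may each explain the Treg genes and were not separated. The donors' sex, which differed between these libraries (Ddx3y at 11.5 FPKM in WT CD44hi), and a difference between single mice stay open and untested.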

How the results depend on the processing

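The settings of genes above 0 in all 4 libraries and of genes at 5 FPKM or more in an iNKT library were added after the data were seen. Over the 9 alternatives, the log2 differences of the named genes kept their direction and side of 2-fold in 4641 cases. In 59 they were now past 2-fold, and none reversed. The 187 values of the difference of the effects kept their direction, though with a pseudocount of 0.1 FPKM that of Angptl2 went from 7.38 to 10.4. Most of this was fixed in advance. Filters, and the choices on rows and small RNA genes, leave the values of a gene on 1 row as they are. The smaller pseudocount, and nearly always TPM scaling, can only enlarge a log2 difference. Of the counts and overlaps, 78 stayed within 1.5 times and 30 did not, and of the overlaps in opposite directions 25 did and 11 did not. Of the list medians 999 stayed the same, 111 moved and 10 reversed. With 1 library per group, no library could be left out.

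TPM scaling multiplies all values (the library sums were 0.362 to 0.380 of the TPM sum), so more genes pass the fixed minimum and the pseudocount weighs less. It gave 1061 genes higher and 613 lower in KO iNKT than WT iNKT, 445 and 243 in KO CD44hi than WT CD44hi, 1857 lower in WT iNKT than WT CD44hi and 590 higher in KO iNKT than KO CD44hi. The overlaps were 125 (higher) and 33 (lower) for the genotype effects and 118 and 995 for the cell type differences, and in opposite directions 58 and 45 (genotype) and 35 and 70 (cell type). A pseudocount of 0.1 FPKM, which by construction gives low values more weight, gave 556 lower in KO iNKT than WT iNKT, 492 higher and 223 lower in KO CD44hi than WT CD44hi, 585 higher in KO iNKT than KO CD44hi, and overlaps of 114 and 34 (genotype) and 126 higher (cell type), with 47 and 48 (genotype) and 41 and 60 (cell type) in opposite directions.

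A filter at 5 FPKM leaves fewer genes. It gave 391 higher in KO iNKT than WT iNKT, 165 higher in KO CD44hi than WT CD44hi, 694 lower in WT iNKT than WT CD44hi, 577 lower in KO iNKT than KO CD44hi, and overlaps of 31 and 10 (genotype) and 337 lower (cell type), with 14 higher in KO iNKT and lower in KO CD44hi, each against its WT, and 24 lower in WT iNKT and higher in KO iNKT, each against its CD44hi. Genes at 5 FPKM or more in an iNKT library, again fewer, gave 391 higher in KO iNKT than WT iNKT, 120 higher and 44 lower in KO CD44hi than WT CD44hi, 358 lower in WT iNKT than WT CD44hi, 243 lower in KO iNKT than KO CD44hi and a cell type overlap of 96 lower, with 14 higher in KO iNKT and lower in KO CD44hi, each against its WT.

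The reversed medians lost members under a filter. The setting of genes at 5 FPKM or more in an iNKT library drops genes low in both iNKT libraries, even where CD44hi is high. Foxp3, for example, was at 0.446 and 0.115 FPKM in WT and KO iNKT but at 53.8 and 13.4 in WT and KO CD44hi. CD8 T cell markers in WT iNKT against WT CD44hi went to 1.59 (filter at 5 FPKM, and genes above 0 in all libraries). Under the filter and among genes at 5 FPKM or more in an iNKT library, NK cell and ILC1 markers in KO CD44hi against WT CD44hi went to 0.42 and NK cell receptors in KO iNKT against WT iNKT to -0.78. Among genes at 5 FPKM or more in an iNKT library, type 2 genes in WT iNKT against WT CD44hi went to 0.53, Treg genes and inhibitory receptors in KO iNKT against KO CD44hi to 0.0209 and 0.85, and plasma cell markers in KO CD44hi against WT CD44hi to -0.21. The medians in this last group did not reverse under the filter at 5 FPKM, so their reversal came with the selection on the iNKT libraries. With both CD44hi libraries thinned to the depth of WT iNKT, 312 genes with a known length were higher and 152 lower in KO CD44hi, against 249 and 123 at full depth.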

Other observations

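Of the 51 genes that passed 2-fold in opposite directions in the genotype pairs, 4 are given here, chosen after their values were seen; the difference between cell types was not tested. Vim, the intermediate filament vimentin, was at 35.6 FPKM in WT iNKT, 119.7 in KO iNKT, 227 in WT CD44hi and 101 in KO CD44hi. S100a6, a calcium-binding protein, was at 84.9, 183, 198 and 93.9 in the same order, and Tiam1, an activator of the GTPase Rac, at 1.89, 18.9, 32.7 and 9.68. Rgs16, a regulator of G protein signalling, was at 0.636, 4.54, 19.3 and 3.99.

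Bmpr1a and Cxxc5 were among the 67 genes higher in both KO libraries and were chosen after their values were seen. Bmpr1a, a BMP receptor, was at 0.330 and 6.38 FPKM in WT and KO iNKT and at 0.458 and 4.93 in WT and KO CD44hi, and Cxxc5, a regulator of Wnt signalling, at 4.59, 28.3, 5.18 and 19.8. Batf3, a transcription factor, was listed at 0 in WT iNKT alone and was at 7.05, 9.30 and 13.8 in KO iNKT, WT CD44hi and KO CD44hi.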
